A study of Rattus norvegicus with 100 samples.

How the data were processed

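Expression was read on 100 Affymetrix RAE230A arrays, 70 of rat uterus and 30 of rat pituitary gland. Per the labels, total RNA was extracted with RNeasy columns and 5 µg was labelled with biotin. The deposited values are linear intensity values per probe set, and array medians lay close together, as scaled values would. The method of summarisation and scaling, and the reason for blank cells, are not given in the sources used here. Of all cells 37.2% were blank. Of the 15923 probe sets, 2892 were blank on all arrays and 6428 had a value on all. Each sample's tissue, treatment and time came from its label, and the number in a title was taken as a replicate number.

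Of the probe sets, 12783 belonged to a single gene, 312 to several genes, 2771 to no gene and 57 were array controls (AFFX). Only probe sets of a single gene entered the tests. For the 1868 genes with several probe sets, the one with the highest mean was used, which gave 10411 genes. Where this probe set passed for a named gene, 102 of 128 values of other probe sets of that gene passed in the same direction. A further 21 went the same way without passing, 5 went the opposite way without passing and 0 passed in the opposite direction. Values were changed to log2(value + 30.4), where 30.4 is the 10th percentile of all values. Blank cells were left out of the fit. A gene was tested in a comparison where each group had at least 3 of 5 values in uterus or 2 of 3 in pituitary, a rule set after the blanks were seen and before any test. Genes with values on every array of one group and none of the other were counted without a fold.

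Per tissue a linear model with a mean for each group was fitted (14 groups in uterus, 10 in pituitary), under R 4.3.3 with limma 3.58.1. Group means and pooled variances left blanks out gene by gene, and limma (squeezeVar) moderated the variances over the genes tested in each comparison. EE was compared with control at each time. The difference of EE effects was tested between any times in each tissue, between 28 and 24 h and between 28 and 4 h in uterus, and between tissues at each shared time in a fit of all 100 arrays. Control groups were compared across times in each tissue. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene passed at an adjusted p under 0.05. Tests of many times at once used an F statistic on the moderated variance.

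The named genes followed a rule set before the data were examined. For each EE comparison these were the 6 largest rises and the 6 largest falls among genes that passed, with non-overlapping groups and a higher group mean above the median of the tissue. Up to 4 members of each list with the smallest adjusted p were added. Always named were Pgr, C3, Esr1, Igf1, Vegfa, Ccnd1, Mki67 and Fos in uterus, and Prl, Gh1, Pgr, Lhb, Fshb, Esr1, Gal and Fos in pituitary. For differences of effects and control times the 6 genes with the smallest adjusted p were taken. The text gives a part of these. Outside the rule, Nr4a1 at 2 h, Hspa5 at 8 h, and Idi1 and Kdr at 24 h in uterus were chosen after values were seen. The comparisons, the lists and most alternatives were also fixed before the data were examined.

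The 31 gene lists held 627 entries, of which 531 matched a gene on the arrays. They covered immediate-early genes, estrogen-responsive genes of uterus and of pituitary, steroid receptors and coregulators, DNA replication, mitosis, ribosome biogenesis, transfer RNA synthetases, endoplasmic reticulum chaperones, cholesterol synthesis, glycolysis, extracellular matrix, angiogenesis, Igf signalling, Wnt signalling, complement, interferon response, glucocorticoid response, the circadian clock and secretory granules. Cell type lists covered smooth muscle, epithelium, macrophages, eosinophils and mast cells, lymphocytes, blood cells, gonadotrophs, lactotrophs and somatotrophs, corticotrophs and melanotrophs, thyrotrophs, and neural lobe and glia. A list with at least 5 measured members was compared with the other genes by the camera statistic of limma, computed on the moderated statistics of all genes tested, with a preset correlation of 0.01 and again with an estimated correlation. The fry test asked whether its members moved, on balance, one way, without comparing them with other genes, and used genes with a value on every array of the tissue. Set p-values were adjusted over the lists and times of a tissue. Counts per list were also made with p-values adjusted over the list alone.

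Array quality was measured by the blank share, the median intensity and the 3'-to-5' log2 differences of the Actb and Gapdh control probe sets, each compared between EE and control by an exact permutation test, two-sided, adjusted over all times and measures. With 3 arrays against 3 the smallest p such a test can give is 0.1. The Actb difference lay between 0.0665 and 1.09 in uterus and between 1.23 and 1.86 in pituitary. No arrays were identical.

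Alternatives fixed beforehand were an offset of 1, values floored at the 10th percentile, arrays centred on their medians, quantile normalization, leaving out the 30% of genes lowest in mean, all probe sets except AFFX, array weights, a prior variance with trend and robust estimation, only the compared groups in the fit, the title number as a replicate block, and leaving out each array in turn. Chosen after seeing the data were blanks counted as 0, only genes with a value on every array compared, leaving out the 3 arrays per tissue with the widest residuals, the Actb 3'-to-5' difference as a covariate, and the level of Krt5 and Krt15 as a covariate. The last was run with blanks counted as 0 on 4 control arrays without values of these genes, and again without these arrays. Array weights came from the gene-by-gene method of limma, because the REML method did not converge. Where a group was left with 1 array, that array was assumed to vary like the other groups.

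The procedure was tested on simulated data with the same arrays, blanks and spread. A true log2 change of 0.5 was found in 90 to 98% of changed genes in uterus, 74 to 84% in pituitary and 56 to 76% for differences of effects. At a log2 change of 1 the shares were at least 96%, with at most 15 false calls in a comparison. Real arrays may give more, as another split of pituitary at 8 h gave 240.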

Results

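Gene expression was measured in the uterus and the pituitary gland of rats from a uterotrophic assay, in which the uterus responds to an estrogenic compound. The compound was ethinylestradiol (EE), a synthetic estrogen, and each EE group had its own control group. Uterus arrays covered 2, 4, 8, 24, 28, 48 and 72 h, with 5 EE and 5 control arrays at each time (70 arrays). Pituitary arrays covered 4, 8, 24, 48 and 72 h, with 3 EE and 3 control arrays at each time (30 arrays). The labels give no dose, route or dosing schedule, and they do not say whether each array stands for a separate animal. The p-values measure only the spread between these samples.

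RNA was labelled with biotin and hybridised to RAE230A arrays of 15923 probe sets, and the deposited values are linear intensities, many of them blank. A uterus array held 9338 to 10677 values, with a median intensity of 94.6 to 108. A pituitary array held 9318 to 10135 values, with a median intensity of 103 to 110. The number of arrays per group limits the precision of every value. Changes are log2 differences, EE minus control, ± the standard error of the fit, with n = 5 per group in uterus and n = 3 per group in pituitary unless other numbers stand beside a value. Differences of effects rest on 3 to 5 arrays per group in uterus and 2 or 3 in pituitary. Folds are ratios of intensity plus an offset of 30.4, which lowers the fold of weak genes. A gene rose or fell where its limma adjusted p was under 0.05.

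The first question was how the uterine transcriptome responds to EE over time. At 2 h, 461 of 7276 genes tested passed, 291 higher and 170 lower. Gadd45g, a growth arrest and DNA damage inducible gene, rose 8.22-fold (log2 3.04 ± 0.12). Inhbb, which encodes the beta B subunit of activins and inhibins, rose 7.93-fold (log2 2.99 ± 0.14, 5 EE and 3 control arrays). Rasd1, a small GTPase of the Ras family, rose 7.86-fold (log2 2.97 ± 0.10). The kinase gene Plk2 rose 6.77-fold (log2 2.76 ± 0.18, 5 EE and 3 control arrays), and Cited4, a co-activator gene, rose by 1.96 ± 0.12. Fos, a subunit of the AP-1 transcription factor, rose 4.72-fold (log2 2.24 ± 0.19), with intensities of 16.3 ± 4.24 in 5 control arrays and 202 ± 87.9 in 5 EE arrays (SD). The growth factor gene Igf1 rose by 0.80 ± 0.09 and the progesterone receptor gene Pgr by 0.57 ± 0.11. Cited2 (-0.97 ± 0.08), the transcription factor gene Sox4 (-0.92 ± 0.09) and the Wnt receptor gene Fzd1 (-0.78 ± 0.09) fell, and of 2 other Sox4 probe sets one was at -0.92 and one at -0.05 (adjusted p = 0.782). The growth factor Vegfa was at 0.25 ± 0.12 (adjusted p = 0.256), and Esr1, Ccnd1 and Mki67 did not pass either.

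Among immediate-early genes at 2 h, 12 of 18 measured members rose, 2 fell and 4 did not pass (13 and 2 adjusted over the list alone). The largest changes there included Cebpb (1.83 ± 0.12), Nr4a1 (1.14 ± 0.11) and Myc (0.93 ± 0.09), all transcription factor genes (camera adjusted p = 9.14e-28, held at adjusted p = 9.33e-06 with an estimated correlation). Of the estrogen-responsive uterine genes, 9 of 16 measured members rose, 0 fell and 7 did not pass (10 and 0 adjusted over the list alone), with camera adjusted p = 9.32e-19, held at adjusted p = 2.03e-06 with an estimated correlation. The ribosome biogenesis genes were already higher, as 14 of 31 measured members rose, 0 fell and 17 did not pass (17 and 0 adjusted over the list alone), with camera adjusted p = 2.83e-14, held at adjusted p = 0.00211 with an estimated correlation. In the list of glucocorticoid-responsive genes, 4 of 12 measured members rose, 1 fell and 7 did not pass (4 and 2 adjusted over the list alone), among them the signalling inhibitor Errfi1 (1.64 ± 0.13), with camera adjusted p = 6.95e-04, held at adjusted p = 0.0412 with an estimated correlation. Set calls were also made for chaperones of the endoplasmic reticulum, higher (adjusted p = 0.352 with an estimated correlation), complement genes, lower (adjusted p = 0.294 with an estimated correlation), and epithelial markers, higher (adjusted p = 0.423 with an estimated correlation). In these 3 lists 2 of 24, 0 of 12 and 0 of 13 genes rose, and 1 complement gene fell. The 2 h count rested partly on the choice of arrays and model, at 263 genes with only the 2 h groups in the fit and at 307 without EE array 12. Among the genes that passed, 63.1% were higher, against 75% after quantile normalization and 78.8% after centring each array on its median.

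By 4 h, 4034 of 6960 genes passed, 1638 higher and 2396 lower (1809 and 2075 after centring arrays on their medians), and 141 of the rises and 68 of the falls were at least 2-fold. Gadd45g (11.7-fold, log2 3.55 ± 0.12), Inhbb (10.9-fold, log2 3.44 ± 0.13, 5 EE and 4 control arrays) and Rasd1 (10.3-fold, log2 3.37 ± 0.11, 5 EE and 4 control arrays) were again the 3 largest rises. S100g, which encodes the calcium-binding protein calbindin-D9k, rose 7.34-fold (log2 2.88 ± 0.14), and Bcat1, a branched-chain amino acid transaminase gene, rose 6.69-fold (log2 2.74 ± 0.20, 5 EE and 4 control arrays). Igf1 rose 4.02-fold (log2 2.01 ± 0.09), Cebpb by 2.34 ± 0.12, Fos by 2.08 ± 0.20 (5 EE and 4 control arrays), Pgr by 1.27 ± 0.11 and Vegfa by 0.81 ± 0.12. Txnip, which encodes an inhibitor of thioredoxin, fell 3.83-fold (log2 -1.94 ± 0.14). Sox4 (-1.83 ± 0.09), Fzd1 (-1.57 ± 0.09) and Pik3ip1, a gene for an inhibitor of phosphoinositide 3-kinase (-1.55 ± 0.11), fell as well. Another Sox4 probe set was only at -0.19 (adjusted p = 0.0264). Esr1, Ccnd1 and Mki67 did not pass at 4 h, although another Ccnd1 probe set was at 0.26 (adjusted p = 0.00391).

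Genes of protein synthesis rose together at 4 h. For ribosome biogenesis, 28 of 29 measured members rose, 0 fell and 1 did not pass (28 and 0 adjusted over the list alone). Tsr1 was at 1.61 ± 0.08 and Gnl3 at 1.63 ± 0.07, and the set had camera adjusted p = 1.20e-20, held at adjusted p = 1.03e-04 with an estimated correlation. Transfer RNA synthetases followed, as 15 of 17 measured members rose, 1 fell and 1 did not pass (15 and 1 adjusted over the list alone). Aars1 was at 1.37 ± 0.08, and the set had camera adjusted p = 8.49e-09, held at adjusted p = 0.00619 with an estimated correlation. Immediate-early genes stayed high, as 14 of 18 measured members rose, 1 fell and 3 did not pass (14 and 1 adjusted over the list alone), with camera adjusted p = 3.65e-08, held at adjusted p = 0.0396 with an estimated correlation. For the estrogen-responsive uterine list, 12 of 16 measured members rose, 0 fell and 4 did not pass (12 and 0 adjusted over the list alone), with camera adjusted p = 7.19e-09, held at adjusted p = 0.00132 with an estimated correlation. Among chaperones of the endoplasmic reticulum 16 of 24 rose and 1 fell (16 and 1 adjusted over the list alone), led by the stress-response transcription factor Atf4 (1.23 ± 0.06), with camera adjusted p = 5.25e-05, lost at adjusted p = 0.165 with an estimated correlation. Of extracellular matrix genes 6 of 37 rose and 16 fell (6 and 17 adjusted over the list alone), and the set was not called (camera adjusted p = 0.183). Igf signalling genes moved mostly down, as 1 of 12 rose and 8 fell (1 and 8 adjusted over the list alone). The receptor gene Igf1r was at -0.62 ± 0.11, and the set had camera adjusted p = 0.312.

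At 8 h, 4469 of 6966 genes passed, 1995 higher and 2474 lower (2047 and 2403 after centring), with 205 rises and 227 falls of at least 2-fold. Kap, the kidney androgen regulated protein gene, rose 9.48-fold (log2 3.25 ± 0.25, 5 EE and 4 control arrays). Tnfaip6, which encodes a hyaluronan-binding protein, rose 8.66-fold (log2 3.11 ± 0.19), S100g by 3.07 ± 0.14, Bcat1 by 2.67 ± 0.19, Inhbb by 2.66 ± 0.12 and the glutathione peroxidase gene Gpx2 by 2.60 ± 0.15. Igf1 rose 4.42-fold (log2 2.15 ± 0.09), complement C3 by 1.19 ± 0.22 (5 EE and 3 control arrays), Fos by 1.22 ± 0.22 (5 EE and 3 control arrays), Pgr by 0.95 ± 0.11, Vegfa by 0.29 ± 0.12 and the cyclin gene Ccnd1 by 0.29 ± 0.08. The proliferation marker Mki67 fell (-0.68 ± 0.20). Ypel3 fell 5.54-fold (log2 -2.47 ± 0.13) and the thioesterase gene Them5 fell 5.51-fold (log2 -2.46 ± 0.16). The sulfotransferase gene Sult1a1 (-2.08 ± 0.16) and Ech1, an enzyme gene of fatty acid breakdown (-1.97 ± 0.10), were other large falls.

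For ribosome biogenesis at 8 h, 31 of 31 measured members rose, 0 fell and 0 did not pass (31 and 0 adjusted over the list alone), with camera adjusted p = 1.35e-19, held at adjusted p = 2.04e-04 with an estimated correlation. Of transfer RNA synthetases 17 of 18 rose and 1 fell (17 and 1 adjusted over the list alone). Yars1 was at 1.56 ± 0.09, and the set had camera adjusted p = 1.53e-09, held at adjusted p = 0.00449 with an estimated correlation. Of the chaperones 19 of 24 rose and 1 fell (19 and 1 adjusted over the list alone). Hspa5, the main chaperone of the endoplasmic reticulum, was at 1.59 ± 0.12, and the set had camera adjusted p = 4.20e-07, lost at adjusted p = 0.0849 with an estimated correlation. In cholesterol synthesis 14 of 17 rose and 1 fell (14 and 1 adjusted over the list alone). The squalene epoxidase gene Sqle was at 1.84 ± 0.22, and the set had camera adjusted p = 8.20e-04, lost at adjusted p = 0.336 with an estimated correlation. Glycolysis genes gave camera adjusted p = 0.0461, lost at adjusted p = 0.352 with an estimated correlation, as 8 of 13 rose and 3 fell (8 and 3 adjusted over the list alone). Of mitosis genes 0 of 16 measured members rose, 11 fell and 5 did not pass (0 and 11 adjusted over the list alone). The topoisomerase gene Top2a was at -0.81 ± 0.21, and the set had camera adjusted p = 0.127. Of the estrogen-responsive uterine genes 11 of 16 rose and 2 fell (11 and 2 adjusted over the list alone), with camera adjusted p = 1.61e-05, held at adjusted p = 0.0241 with an estimated correlation. The 3'-to-5' log2 difference of the Actb control probe sets, a measure of RNA integrity, was 0.225 ± 0.0941 with EE and 0.510 ± 0.114 in controls (SD, n = 5, exact permutation p = 0.00794, 0.0544 adjusted). The blank share in percent was 38.2 ± 0.975 with EE and 34.5 ± 0.836 in controls (SD, n = 5, exact permutation p = 0.00794, 0.0544 adjusted).

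**Figure D1:**
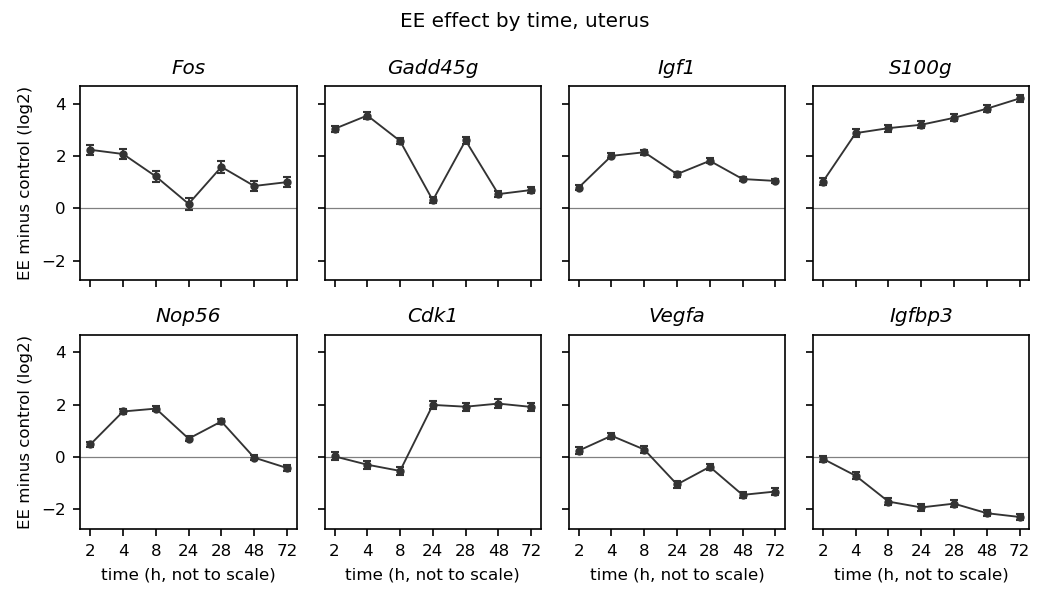
EE minus control log2 difference (vertical axis) of 8 genes against time (horizontal axis, not to scale) in uterus, with points for the fit and bars for its standard error, n = 5 arrays per group except 3 or 4 control arrays for Fos at 4 to 28 h and 4 for Gadd45g at 28 h. The difference was high for Fos and Gadd45g at 2 to 8 h and again at 28 h, whereas for Cdk1 it was high from 24 h on.

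At 24 h, 4191 of 7087 genes passed, 1760 higher and 2431 lower (2013 and 2010 after centring), with 161 rises and 90 falls of at least 2-fold. Genes of stratified epithelium joined the largest rises, with the keratin gene Krt6c up 18.8-fold (log2 4.23 ± 0.69), Sprr1a, which encodes a protein of the cornified envelope, up 8.34-fold (log2 3.06 ± 0.45) and the keratin gene Krt10 up 7.66-fold (log2 2.94 ± 0.53). Sprr1a had risen by 8 h (2.14 ± 0.45), and Krt6c was at 1.69 ± 0.69 at 2 h (adjusted p = 0.138). Across the 66 uterus arrays with values of the basal keratin genes Krt5 and Krt15, the residuals of 5 such genes varied with theirs (r = 0.766, rho = 0.791, both permutation p = 1e-05, r = 0.744 without the 2 farthest arrays). Kap rose 14-fold (log2 3.81 ± 0.27, 5 EE and 3 control arrays), C3 rose 13.5-fold (log2 3.76 ± 0.22, 5 EE and 3 control arrays) and S100g rose 9.16-fold (log2 3.20 ± 0.14). Igf1 (1.31 ± 0.09), Mki67 (1.71 ± 0.20), the estrogen receptor gene Esr1 (0.33 ± 0.11) and Pgr (0.31 ± 0.11) rose, while Vegfa fell (-1.04 ± 0.12). Fos was at 0.17 ± 0.22 (adjusted p = 0.517, 5 EE and 3 control arrays). Them5 fell 4.79-fold (log2 -2.26 ± 0.16), the glutathione transferase gene Gstm7 4.48-fold (log2 -2.16 ± 0.18, 4 EE and 5 control arrays) and Enpp2, which encodes autotaxin, 4.40-fold (log2 -2.14 ± 0.12). The Igf-binding protein gene Igfbp3 (-1.92 ± 0.12) also fell.

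Cell division genes were up at 24 h. In the mitosis list 16 of 16 measured members rose, 0 fell and 0 did not pass (16 and 0 adjusted over the list alone). The kinase gene Cdk1 was at 1.99 ± 0.16 and Cks2 at 2.26 ± 0.18, and the set had camera adjusted p = 6.81e-15, lost at adjusted p = 0.0742 with an estimated correlation. For DNA replication 20 of 21 measured members rose, 0 fell and 1 did not pass (20 and 1 adjusted over the list alone). Thymidine kinase Tk1 was at 1.79 ± 0.14, and the set had camera adjusted p = 3.23e-12, lost at adjusted p = 0.0805 with an estimated correlation. In cholesterol synthesis 12 of 12 measured members rose, 0 fell and 0 did not pass (12 and 0 adjusted over the list alone). Idi1 was at 1.36 ± 0.16, Fdps at 2.05 ± 0.16, and the set had camera adjusted p = 1.28e-09, held at adjusted p = 0.0412 with an estimated correlation. Interferon-responsive genes gave camera adjusted p = 2.90e-05, lost at adjusted p = 0.152 with an estimated correlation, as 13 of 15 rose and 0 fell (13 and 0 adjusted over the list alone). Glycolysis genes gave camera adjusted p = 2.40e-05, lost at adjusted p = 0.0559 with an estimated correlation, as 9 of 13 rose and 0 fell (9 and 0 adjusted over the list alone). Angiogenesis genes were lower, as 1 of 17 rose and 10 fell (1 and 10 adjusted over the list alone). The Vegf receptor gene Kdr was at -0.62 ± 0.11, and the set had camera adjusted p = 0.0200, lost at adjusted p = 0.0805 with an estimated correlation. In Wnt signalling 3 of 18 rose and 13 fell (3 and 13 adjusted over the list alone), with camera adjusted p = 0.0105, lost at adjusted p = 0.0687 with an estimated correlation. For secretory granule genes 0 of 9 rose and 6 fell (0 and 6 adjusted over the list alone), with camera adjusted p = 0.0331, lost at adjusted p = 0.250 with an estimated correlation.

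Further set calls at 24 h were for estrogen-responsive uterine genes, as 9 of 17 rose and 3 fell (9 and 3 adjusted over the list alone), with camera adjusted p = 0.0189, lost at adjusted p = 0.172 with an estimated correlation. Transfer RNA synthetases were higher, as 15 of 18 rose and 0 fell (15 and 0 adjusted over the list alone), with camera adjusted p = 1.36e-04, lost at adjusted p = 0.0783 with an estimated correlation. Chaperone genes were higher too, as 16 of 24 rose and 4 fell (16 and 4 adjusted over the list alone), with camera adjusted p = 5.28e-06, lost at adjusted p = 0.122 with an estimated correlation. Epithelial markers were higher, as 8 of 12 rose and 2 fell (8 and 2 adjusted over the list alone), with camera adjusted p = 0.0206, lost at adjusted p = 0.387 with an estimated correlation. The median intensity of an array was 96.8 ± 1.26 with EE and 102 ± 1.91 in controls (SD, n = 5, exact permutation p = 0.00794, 0.0544 adjusted).

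At 28 h, 4396 of 6998 genes passed, 1985 higher and 2411 lower (2180 and 2124 after centring), with 183 rises and 158 falls of at least 2-fold. Rasd1, one of the largest early rises, was again among the largest (8.41-fold, log2 3.07 ± 0.10), and Fos rose by 1.58 ± 0.22 (5 EE and 3 control arrays). Kap rose 14-fold (log2 3.80 ± 0.24), S100g 11-fold (log2 3.46 ± 0.14) and Sprr1a 7.82-fold (log2 2.97 ± 0.48, 5 EE and 4 control arrays). The keratin genes Krt14 (3.51 ± 0.69, 3 EE and 4 control arrays) and Krt13 (3.42 ± 0.55, 3 EE and 3 control arrays) passed, but had values only on the 3 EE arrays with Krt6c at 743 to 1047, whereas the 2 others had 18.1 and 32.4. With blanks counted as 0 Krt14 was at 1.58 (adjusted p = 0.195). Igf1 (1.82 ± 0.09), Mki67 (1.72 ± 0.20) and Pgr (0.86 ± 0.11) rose and Vegfa fell (-0.37 ± 0.12). Large falls were those of Them5 (-2.44 ± 0.16), Enpp2 (-2.31 ± 0.12), Tgfbi (-2.30 ± 0.12) and the prohormone-processing enzyme gene Cpe (-2.21 ± 0.11). C3 had intensities of 26.7 ± 3.37 in 2 control arrays and 1074 ± 246 in 5 EE arrays (SD), and was not tested for want of control values.

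Estrogen-responsive uterine genes kept a call with both correlations, as 9 of 16 measured members rose, 2 fell and 5 did not pass (9 and 2 adjusted over the list alone), with camera adjusted p = 8.11e-05, held at adjusted p = 0.0399 with an estimated correlation. The same held for ribosome biogenesis, as 23 of 30 measured members rose, 0 fell and 7 did not pass (23 and 0 adjusted over the list alone), with camera adjusted p = 9.41e-08, held at adjusted p = 0.0399 with an estimated correlation. Of mitosis genes 16 of 16 rose and 0 fell (16 and 0 adjusted over the list alone), with camera adjusted p = 1.12e-11, lost at adjusted p = 0.109 with an estimated correlation. DNA replication genes gave camera adjusted p = 1.42e-07, lost at adjusted p = 0.179 with an estimated correlation, as 20 of 21 rose and 0 fell (20 and 0 adjusted over the list alone). Cholesterol synthesis genes gave camera adjusted p = 4.68e-08, lost at adjusted p = 0.0687 with an estimated correlation, as 12 of 12 rose and 0 fell (12 and 0 adjusted over the list alone). Complement genes were lower, as 1 of 10 rose and 8 fell (1 and 8 adjusted over the list alone). The C1 inhibitor gene Serping1 was at -1.72 ± 0.11, and the set had camera adjusted p = 0.00460, lost at adjusted p = 0.160 with an estimated correlation. In Wnt signalling 2 of 20 rose and 13 fell (2 and 13 adjusted over the list alone). Dkk3 was at -1.57 ± 0.11, and the set had camera adjusted p = 0.00799, lost at adjusted p = 0.0635 with an estimated correlation. The Actb 3'-to-5' difference was 0.197 ± 0.0735 with EE and 0.441 ± 0.0782 in controls (SD, n = 5, exact permutation p = 0.00794, 0.0544 adjusted).

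At 48 h, 4018 of 7035 genes passed, 1700 higher and 2318 lower (1908 and 2031 after centring), with 174 rises and 90 falls of at least 2-fold. C3 had the largest rise, 37.3-fold (log2 5.22 ± 0.22, 5 EE and 3 control arrays), with intensities of 31.5 ± 6.49 in 3 control arrays and 2317 ± 476 in 5 EE arrays (SD). S100g rose 14-fold (log2 3.81 ± 0.14), Kap 12.6-fold (log2 3.66 ± 0.24) and the keratin gene Krt6c 11-fold (log2 3.46 ± 0.69). Ccl11, which encodes the eosinophil attractant eotaxin, rose 9.61-fold (log2 3.26 ± 0.17), and Sprr1a rose by 2.75 ± 0.45. Mki67 (2.05 ± 0.21, 5 EE and 4 control arrays), Igf1 (1.12 ± 0.09), Fos (0.86 ± 0.19) and Esr1 (0.25 ± 0.11) rose and Vegfa fell (-1.44 ± 0.12). Pgr was at 0.24 ± 0.11 (adjusted p = 0.0605). Them5 fell 6.09-fold (log2 -2.61 ± 0.19, 3 EE and 5 control arrays) and Cpxm1, of the carboxypeptidase family, fell 5.73-fold (log2 -2.52 ± 0.16). Enpp2 (-2.16 ± 0.12), Igfbp3 (-2.14 ± 0.12) and the sodium channel gene Scn7a (-1.93 ± 0.32) fell as well.

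Glycolysis genes kept their call at 48 h, as 11 of 13 measured members rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone). The lactate dehydrogenase gene Ldha was at 1.29 ± 0.09, and the set had camera adjusted p = 2.96e-06, held at adjusted p = 0.0396 with an estimated correlation. In the mitosis list 15 of 15 rose and 0 fell (15 and 0 adjusted over the list alone), with camera adjusted p = 1.24e-13, lost at adjusted p = 0.0805 with an estimated correlation. For interferon-responsive genes 13 of 14 measured members rose, 0 fell and 1 did not pass (13 and 0 adjusted over the list alone). The antiviral gene Mx1 was at 2.02 ± 0.13, and the set had camera adjusted p = 6.78e-08, lost at adjusted p = 0.0697 with an estimated correlation. Macrophage markers were higher, as 9 of 10 measured members rose, 1 fell and 0 did not pass (9 and 1 adjusted over the list alone). The lysozyme gene Lyz2 was at 1.73 ± 0.15, and the set had camera adjusted p = 6.06e-07, lost at adjusted p = 0.0783 with an estimated correlation. Steroid receptor and cofactor genes were lower, as 1 of 8 measured members rose, 6 fell and 1 did not pass (2 and 6 adjusted over the list alone). The glucocorticoid receptor gene Nr3c1 was at -0.73 ± 0.10, and the set had camera adjusted p = 0.0442, lost at adjusted p = 0.147 with an estimated correlation. Epithelial markers gave camera adjusted p = 1.98e-06, lost at adjusted p = 0.0854 with an estimated correlation, as 10 of 13 rose and 1 fell (10 and 1 adjusted over the list alone). The 3'-to-5' differences were 0.248 ± 0.133 with EE and 0.615 ± 0.180 in controls (SD, n = 5, exact permutation p = 0.00794, 0.0544 adjusted) for Actb, and 0.341 ± 0.0613 with EE and 0.550 ± 0.112 in controls (SD, n = 5, exact permutation p = 0.00794, 0.0544 adjusted) for Gapdh.

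At 72 h, 4106 of 6832 genes passed, 1597 higher and 2509 lower (1864 and 2091 after centring), with 194 rises and 96 falls of at least 2-fold. Krt6c rose 19.9-fold (log2 4.31 ± 0.69), S100g 18.4-fold (log2 4.20 ± 0.14), Ccl11 16.6-fold (log2 4.05 ± 0.17) and Kap 15.8-fold (log2 3.98 ± 0.24). Sprr1a rose by 3.33 ± 0.45, and Ceacam1, a cell adhesion gene, by 3.27 ± 0.13. C3 had intensities of 35.1 ± 5.49 in 2 control arrays and 3622 ± 702 in 5 EE arrays (SD), and was not tested for want of control values. Cpxm1 fell 9.72-fold (log2 -3.28 ± 0.16) and Igfbp3 fell 4.88-fold (log2 -2.29 ± 0.12). Enpp2 (-2.20 ± 0.12) and the imprinted non-coding RNA H19 (-2.0 ± 0.14) fell. Mki67 (1.60 ± 0.21, 5 EE and 4 control arrays), Igf1 (1.05 ± 0.09), Fos (1.0 ± 0.19) and Pgr (0.49 ± 0.11) were still higher and Vegfa lower (-1.32 ± 0.12). Mki67 had intensities of 147 ± 23.4 with EE and 27.9 ± 6.49 in controls (SD), and 134 and 152 at 2 h, so its difference at 72 h goes with a fall in the controls.

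Extracellular matrix genes, smooth muscle markers and macrophage markers were called higher as sets at 72 h, and none of these calls held with an estimated correlation. In the extracellular matrix list 20 of 37 measured members rose, 8 fell and 9 did not pass (20 and 9 adjusted over the list alone). The inhibitor gene Timp1 was at 1.32 ± 0.08, Timp3 at -1.37 ± 0.09, and the set had camera adjusted p = 0.00569, lost at adjusted p = 0.165 with an estimated correlation. For smooth muscle markers 8 of 14 measured members rose, 1 fell and 5 did not pass (8 and 1 adjusted over the list alone). The actin gene Actg2 was at 1.08 ± 0.11, and the set had camera adjusted p = 0.0115, lost at adjusted p = 0.336 with an estimated correlation. Among macrophage markers 9 of 10 rose and 0 fell (9 and 0 adjusted over the list alone), with camera adjusted p = 1.39e-08, lost at adjusted p = 0.0507 with an estimated correlation. Epithelial markers were higher, as 11 of 13 measured members rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone). Krt19 was at 2.93 ± 0.23, the transcription factor Elf3 at 2.56 ± 0.14, and the set had camera adjusted p = 4.20e-07, lost at adjusted p = 0.0783 with an estimated correlation. Glycolysis genes kept a call, as 11 of 13 rose and 1 fell (11 and 1 adjusted over the list alone), with camera adjusted p = 3.42e-06, held at adjusted p = 0.0396 with an estimated correlation. Ribosome biogenesis genes were now lower, as 2 of 27 measured members rose, 19 fell and 6 did not pass (2 and 21 adjusted over the list alone). Nolc1 was at -0.81 ± 0.08, and the set had camera adjusted p = 0.0206, lost at adjusted p = 0.352 with an estimated correlation. The Actb 3'-to-5' difference was 0.317 ± 0.144 with EE and 0.668 ± 0.268 in controls (SD, n = 5, exact permutation p = 0.0317, 0.147 adjusted), and the median intensity was 98.4 ± 2.30 with EE and 103 ± 1.07 in controls (SD, n = 5, exact permutation p = 0.00794, 0.0544 adjusted).

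Lists with no set call in uterus at any time held single genes that moved. At 72 h, 2 of 13 rose and 7 fell (2 and 7 adjusted over the list alone) in Igf signalling, with the binding protein gene Igfbp2 at 2.30 ± 0.25. Of the pituitary estrogen-responsive genes 2 of 7 rose and 2 fell (2 and 2 adjusted over the list alone), with the activin-binding protein gene Fst lower at 4 h (-0.92 ± 0.10). Circadian clock genes moved at 8 h, when 6 of 10 rose and 4 fell (6 and 4 adjusted over the list alone), with Dbp at -1.67 ± 0.13 and Nr1d2 at -1.64 ± 0.12. Among neural lobe and glial markers 1 of 6 rose and 2 fell (1 and 2 adjusted over the list alone) at 72 h, and among gonadotroph markers 1 of 5 rose and 2 fell (1 and 2 adjusted over the list alone). Lists with under 5 measured members had no set test. There, lymphocyte markers held Lck, a kinase of T cells, at -0.19 ± 0.06 at 8 h, and at 72 h 0 of 2 rose and 0 fell (0 and 0 adjusted over the list alone). Of blood cell markers 0 of 2 rose and 2 fell (0 and 2 adjusted over the list alone), with the globin gene Hbb at -0.74 ± 0.24. Eosinophil and mast cell markers had 0 of 2 members higher and 0 lower (0 and 0 adjusted over the list alone). For lactotroph and somatotroph markers 0 of 2 rose and 2 fell (0 and 2 adjusted over the list alone), and for thyrotroph markers 1 of 3 rose and 1 fell (1 and 1 adjusted over the list alone). Corticotroph and melanotroph markers had 0 of 1 members higher and 0 lower (0 and 0 adjusted over the list alone) at 24 h.

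**Figure D2:**
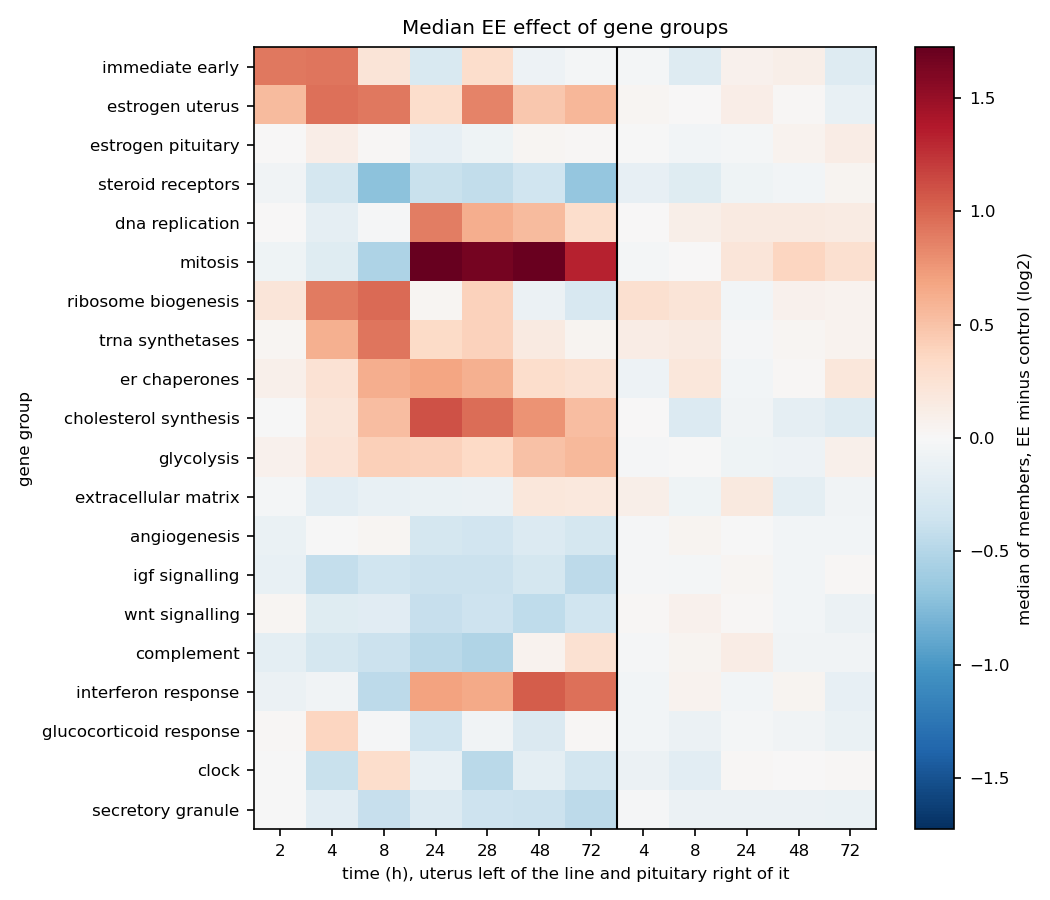
Median EE minus control log2 difference (colour) of the measured members of 20 gene groups (vertical axis) at each time (horizontal axis), for uterus on the left and pituitary on the right, with 5 or more members needed for a cell and grey where fewer were measured. Mitosis genes were high in uterus from 24 h on, and ribosome biogenesis genes were high at 4 and 8 h.

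Over all 7 times, 6391 genes were tested at each time in uterus. Of these 358 passed at no time and 135 at all 7, of which 47 were higher each time and 66 lower each time. In all, 1450 genes were higher at some time and lower at another. At 4 and 8 h, 1327 genes rose at both against 470 by chance, and 48 passed in opposite directions. At 4 and 72 h, 871 genes passed in opposite directions, against 1135 by chance.

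The EE effect differed between times in uterus for 5210 of 6391 genes. Gnl3, a nucleolar GTPase gene, had effects of 1.63 at 4 h and -0.56 at 72 h (adjusted p = 1.37e-31). Gadd45g had 3.55 at 4 h and 0.31 at 24 h (adjusted p = 3.00e-29), and Rasd1 3.37 at 4 h and 0.68 at 72 h (adjusted p = 4.92e-29).

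Between 24 and 28 h the effect changed for 568 of 6863 genes, more positive at 28 h in 349 and more negative in 219. Several of the largest early rises had the smallest adjusted p. The 28 h effect exceeded the 24 h effect by 2.29 ± 0.17 for Gadd45g, 2.07 ± 0.15 for Rasd1, 1.90 ± 0.17 for Cited4, 1.65 ± 0.17 for Inhbb and 1.41 ± 0.14 for Enc1. For Sox4 the difference was -1.36 ± 0.13. Immediate-early genes had more positive effects at 28 h in 11 of 18 (12 adjusted over the list alone), with camera adjusted p = 1.22e-12, held at adjusted p = 0.00460 with an estimated correlation. The estrogen-responsive uterine genes did so in 8 of 16 (8 adjusted over the list alone), with camera adjusted p = 2.28e-09, held at adjusted p = 0.00204 with an estimated correlation. Ribosome biogenesis genes did so in 12 of 29 (17 adjusted over the list alone), with camera adjusted p = 1.19e-12, held at adjusted p = 0.00397 with an estimated correlation. Replication genes had more negative effects on balance, with camera adjusted p = 0.0179, lost at adjusted p = 0.556 with an estimated correlation, although none passed alone.

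Compared with 4 h, the effect at 28 h differed for 2428 of 6776 genes, 1235 more positive and 1193 more negative. The differences were 2.37 ± 0.23 for the cell cycle phosphatase gene Cdkn3, 2.05 ± 0.16 for Crip1, 2.01 ± 0.19 for Tk1 and 1.93 ± 0.18 for Dbi. They were -1.68 ± 0.16 for Cpe and -1.39 ± 0.14 for Tnfrsf12a. Mitosis genes had more positive effects in 16 of 16 (16 adjusted over the list alone), with camera adjusted p = 1.13e-19, held at adjusted p = 0.0312 with an estimated correlation. Ribosome biogenesis genes had more negative effects in 22 of 29 (22 adjusted over the list alone), with camera adjusted p = 4.40e-08, held at adjusted p = 0.0281 with an estimated correlation. Angiogenesis genes had more negative effects in 7 of 16 (7 adjusted over the list alone), with camera adjusted p = 0.00570, held at adjusted p = 0.0391 with an estimated correlation. Cholesterol synthesis genes had more positive effects in 12 of 12 (12 adjusted over the list alone), with camera adjusted p = 1.80e-08, lost at adjusted p = 0.0570 with an estimated correlation.

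**Figure D3:**
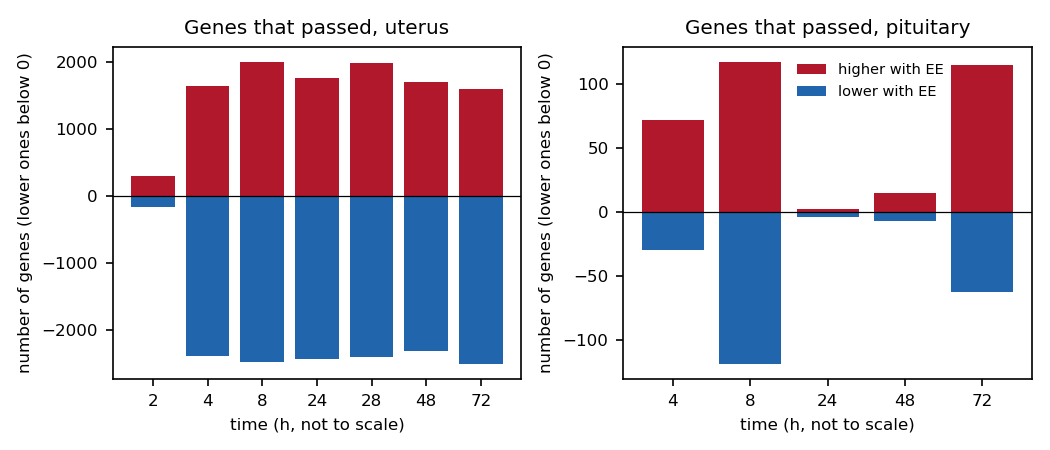
Number of genes (vertical axis) that were higher (red) or lower (blue, drawn below 0) with EE at each time (horizontal axis, not to scale) in uterus (left, n = 5 arrays per group) and pituitary (right, n = 3 arrays per group), with different vertical scales. Counts in uterus stood between 4018 and 4469 from 4 h on, against 6 to 236 in pituitary.

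The next question was how the pituitary gland, the source of the gonadotropins, responds. At 4 h, 102 of 6860 genes passed, 72 higher and 30 lower. Ass1, argininosuccinate synthase of the urea cycle, rose 3.37-fold (log2 1.75 ± 0.11). Cited4 (1.14 ± 0.18), Litaf (1.14 ± 0.15) and the snoRNP protein gene Nop56 (1.07 ± 0.11) rose. Pou1f1, the transcription factor of somatotrophs, lactotrophs and thyrotrophs, fell 2.13-fold (log2 -1.09 ± 0.13). Vsnl1 (-0.88 ± 0.13, with its other probe set at -0.40, adjusted p = 0.126), the growth factor gene Vegfc (-0.62 ± 0.14) and the transcription factor Neurod1 (-0.57 ± 0.12) fell. Prolactin (Prl) was at 0.08 ± 0.15 (adjusted p = 0.927), and growth hormone (Gh1) at 0.13 ± 0.11 (adjusted p = 0.818). Of ribosome biogenesis genes 6 of 26 measured members rose, 0 fell and 20 did not pass (13 and 0 adjusted over the list alone), with camera adjusted p = 2.19e-18, held at adjusted p = 9.07e-04 with an estimated correlation. For transfer RNA synthetases 0 of 17 rose and 0 fell (3 and 0 adjusted over the list alone), with camera adjusted p = 2.83e-05, held at adjusted p = 0.0462 with an estimated correlation. Chaperone genes were lower on balance, as 0 of 24 rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.0479, lost at adjusted p = 0.631 with an estimated correlation.

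The 4 h pituitary count was 26 with only the 4 h groups in the fit and 194 with array weights. Leaving out 1 array gave 54 genes without control array 16, 64 without control array 17 and 56 without EE array 23.

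At 8 h in pituitary, 236 of 6709 genes passed, 117 higher and 119 lower. Pdlim3 (1.21 ± 0.13), Ass1 (1.12 ± 0.11), Cep44 (0.97 ± 0.12) and Nop56 (0.85 ± 0.11) had the largest rises, and Pgr rose by 0.66 ± 0.10. Plagl1, an imprinted zinc finger gene, fell 2.12-fold (log2 -1.08 ± 0.19). Sec14l3 (-1.02 ± 0.29), Ghrhr, the receptor for growth hormone releasing hormone (-0.76 ± 0.14), and the endothelin-converting enzyme gene Ece1 (-0.70 ± 0.17) fell. Ribosome biogenesis genes were higher, as 5 of 26 measured members rose, 0 fell and 21 did not pass (12 and 0 adjusted over the list alone), with camera adjusted p = 7.44e-09, held at adjusted p = 0.0112 with an estimated correlation. Cholesterol synthesis genes were lower, as 0 of 16 measured members rose, 2 fell and 14 did not pass (0 and 6 adjusted over the list alone). Idi1 was at -0.60 ± 0.16 (its other probe set at -0.20, adjusted p = 0.501), and the set had camera adjusted p = 1.70e-04, held at adjusted p = 0.0217 with an estimated correlation. Transfer RNA synthetases gave camera adjusted p = 0.00135, lost at adjusted p = 0.126 with an estimated correlation, as 2 of 17 rose and 0 fell (7 and 0 adjusted over the list alone). Among chaperones 3 of 24 rose and 0 fell (10 and 0 adjusted over the list alone). Pdia4 was at 0.55 ± 0.11, and the set had camera adjusted p = 1.20e-05, lost at adjusted p = 0.159 with an estimated correlation. Lactotroph and somatotroph markers were lower, as 0 of 8 rose and 2 fell (0 and 2 adjusted over the list alone), with camera adjusted p = 0.00941, lost at adjusted p = 0.0758 with an estimated correlation. Clock genes were lower too, as 0 of 11 rose and 1 fell (0 and 4 adjusted over the list alone), with camera adjusted p = 0.00581, lost at adjusted p = 0.0793 with an estimated correlation. The glucocorticoid-responsive list gave camera adjusted p = 0.0385, lost at adjusted p = 0.395 with an estimated correlation, as 0 of 11 rose and 1 fell (0 and 2 adjusted over the list alone).

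Arrays weighed heavily on the 8 h pituitary count, which was 58 without EE array 34, 72 without control array 28, 128 without control array 26, 153 without EE array 32 and 533 without EE array 33. It was 9 with only the 8 h groups in the fit, 8 without the arrays of widest residuals and 512 with the Actb 3'-to-5' difference as a covariate.

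At 24 h in pituitary, 6 of 6877 genes passed, and 389 had an unadjusted p under 0.05. Pclaf, which encodes a partner of the replication clamp, rose by 0.65 ± 0.12, and the transcription factor Gata2 by 0.58 ± 0.11. Plagl1 fell 2.03-fold (log2 -1.02 ± 0.19) and Gnrhr, the receptor for gonadotropin-releasing hormone, fell 1.81-fold (log2 -0.86 ± 0.17). Fdx1, the electron donor of steroidogenic enzymes (-0.72 ± 0.13), and Tnfrsf12a (-0.54 ± 0.10) fell. Fshb, the beta subunit of follicle-stimulating hormone, was at -1.49 ± 0.37 (adjusted p = 0.174). DNA replication genes were higher as a set although no member passed alone, as 0 of 20 rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 4.18e-05, held at adjusted p = 0.0318 with an estimated correlation. Mitosis genes did likewise, as 0 of 15 rose and 0 fell (4 and 0 adjusted over the list alone), with camera adjusted p = 1.20e-06, held at adjusted p = 0.0484 with an estimated correlation. Thyrotroph markers gave camera adjusted p = 0.0361, lost at adjusted p = 0.243 with an estimated correlation, as 1 of 5 rose and 0 fell (1 and 0 adjusted over the list alone). The 24 h count was 0 in limma without EE array 43, 1 without control array 40, control array 42 or EE array 46, and 3 without EE array 44. It was 0 with floored values, 2 with only the 24 h groups in the fit and 13 with array weights.

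At 48 h in pituitary, 22 of 6882 genes passed, 15 higher and 7 lower. Among the 6 largest rises were the cell division genes Top2a (0.61 ± 0.11), Pclaf (0.60 ± 0.12), Spc25 (0.54 ± 0.10) and cyclin B1, Ccnb1 (0.53 ± 0.10). Gnrhr fell 2.33-fold (log2 -1.22 ± 0.17) and Plagl1 fell 2.16-fold (log2 -1.11 ± 0.19). In the mitosis list 2 of 14 measured members rose, 0 fell and 12 did not pass (12 and 0 adjusted over the list alone), with camera adjusted p = 2.57e-16, held at adjusted p = 0.00331 with an estimated correlation. For DNA replication 1 of 21 rose and 0 fell (2 and 0 adjusted over the list alone), with camera adjusted p = 4.18e-05, held at adjusted p = 0.0318 with an estimated correlation. Gonadotroph markers were lower, as 0 of 8 measured members rose, 1 fell and 7 did not pass (0 and 3 adjusted over the list alone). Fshb was at -1.42 ± 0.37 (adjusted p = 0.0971), and the set had camera adjusted p = 0.00436, lost at adjusted p = 0.0816 with an estimated correlation. Secretory granule genes were lower as well, as 0 of 16 rose and 0 fell (0 and 2 adjusted over the list alone), with camera adjusted p = 9.72e-04, lost at adjusted p = 0.159 with an estimated correlation.

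The 48 h pituitary count was 184 with array weights, 40 with blanks counted as 0 and 37 without the arrays of widest residuals. It was 9 without control array 64, 12 without control array 66, 13 without EE array 68 and 10 without EE array 69.

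At 72 h in pituitary, 178 of 6663 genes passed, 115 higher and 63 lower. The folding enzyme gene Fkbp11 (1.12 ± 0.15), Olfm3 (1.09 ± 0.12), Trhr, the receptor for thyrotropin-releasing hormone (0.96 ± 0.15), Tspan2 (0.94 ± 0.19), Fgf13 (0.91 ± 0.16) and Tmem248 (0.88 ± 0.14) had the largest rises, and Pgr rose by 0.56 ± 0.10. Probe sets disagreed for Tmem248, where the other was at -0.40 (adjusted p = 0.258). For Tspan2 the other was at 0.37 (adjusted p = 0.0785), and for Trhr the others were at 0.74 (adjusted p = 0.00376) and 0.34 (adjusted p = 0.287). Fos fell 4.19-fold (log2 -2.07 ± 0.38) and Gnrhr fell 2.96-fold (log2 -1.57 ± 0.17). The antiviral gene Rsad2 (-1.10 ± 0.30), Necab2 (-0.99 ± 0.11), Rgs2 (-0.88 ± 0.16) and Plagl1 (-0.83 ± 0.19) fell. The luteinizing hormone beta gene Lhb was at -0.59 ± 0.17 (adjusted p = 0.0553) and Prl at 0.21 ± 0.15 (adjusted p = 0.599). Neither Prl nor Gh1 passed at any time, but both were among the 16 brightest probe sets on every array, and whether such values are saturated was not tested. Esr1 and Gal were not tested at 4, 8 and 24 h for want of values. Immediate-early genes were lower, as 0 of 18 measured members rose, 2 fell and 16 did not pass (0 and 7 adjusted over the list alone), with camera adjusted p = 4.49e-04, held at adjusted p = 0.0217 with an estimated correlation. In the 72 h controls the 18 members averaged 0.44 log2 above the other control arrays (3 against 12 arrays, exact permutation p = 0.0132). Mitosis genes were higher, as 2 of 15 rose and 0 fell (9 and 0 adjusted over the list alone), with camera adjusted p = 2.09e-07, held at adjusted p = 0.0372 with an estimated correlation. Cholesterol synthesis genes were lower, as 0 of 16 rose and 4 fell (0 and 7 adjusted over the list alone), with camera adjusted p = 2.09e-05, held at adjusted p = 0.0112 with an estimated correlation. Chaperones were higher, as 4 of 24 rose and 0 fell (6 and 0 adjusted over the list alone), with camera adjusted p = 2.12e-06, lost at adjusted p = 0.136 with an estimated correlation.

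The 72 h pituitary count was 336 with array weights, 102 without control array 73, 89 without control array 76, 87 without EE array 81, 115 without EE array 82 and 99 without EE array 83. Over the 5 times, 5960 of 6407 genes tested at each time passed at none, 13 passed at 3 and 1 at 4. In all, 33 genes rose at both 4 and 8 h, against 1.25 by chance. The EE effect differed between times for 70 genes in pituitary. The clearest were Ass1, with 1.75 at 4 h and -0.59 at 72 h (adjusted p = 7.06e-11), Gnrhr, with 0.53 at 8 h and -1.57 at 72 h (adjusted p = 4.69e-05), and Pou1f1, with 0.16 at 72 h and -1.09 at 4 h (adjusted p = 5.91e-04). That count of 70 became 210 with array weights, 40 without control array 16 of 4 h, 45 without control array 26 of 8 h, 116 without EE array 33 of 8 h and 46 without EE array 81 of 72 h.

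**Figure D4:**
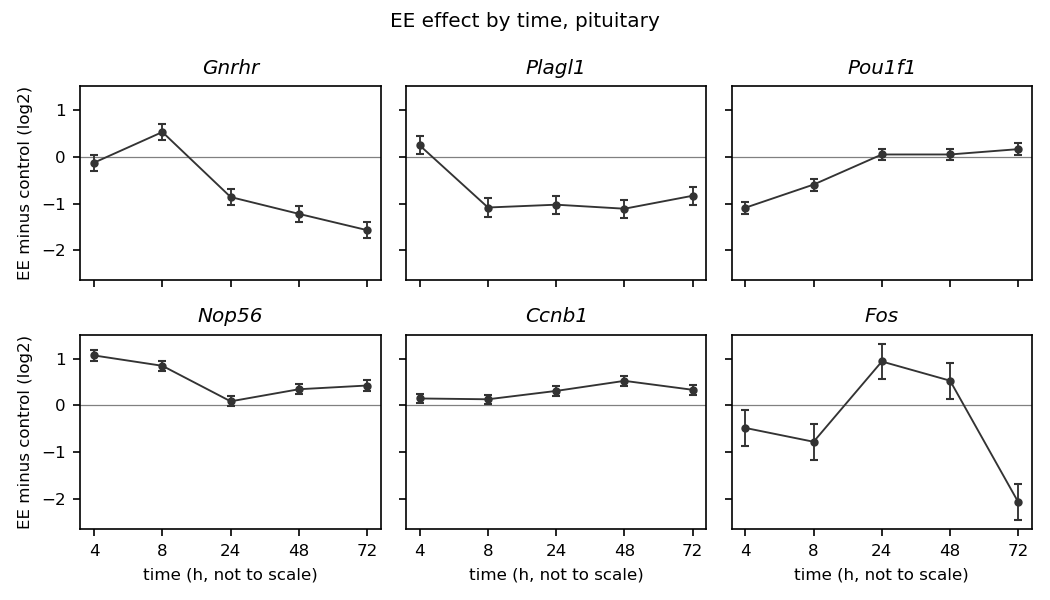
EE minus control log2 difference (vertical axis) of 6 genes against time (horizontal axis, not to scale) in pituitary, with points for the fit and bars for its standard error, n = 3 arrays per group. Plagl1 fell at 8 h and later and Gnrhr at 24 h and later, and Nop56 was highest at 4 and 8 h.

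Lists not called as a set in pituitary at any time, with their 72 h counts, were the following. The uterine estrogen-responsive list had 1 of 8 members higher and 0 lower (1 and 1 adjusted over the list alone), and Inhbb rose at 4 h (0.46 ± 0.11). The angiogenesis list had 0 of 14 members higher and 0 lower (0 and 0 adjusted over the list alone), and the hypoxia-inducible factor gene Hif1a rose at 4 h (0.87 ± 0.09). Steroid receptors had 1 of 7 members higher and 0 lower (2 and 3 adjusted over the list alone) and glycolysis genes 0 of 12 members higher and 1 lower (0 and 1 adjusted over the list alone). Pituitary estrogen-responsive genes had 1 of 12 members higher and 1 lower (3 and 2 adjusted over the list alone). Complement genes had 0 of 9 members higher and 0 lower (0 and 0 adjusted over the list alone) and interferon-responsive genes 0 of 11 members higher and 1 lower (0 and 1 adjusted over the list alone). Igf signalling genes had 0 of 11 members higher and 0 lower (0 and 1 adjusted over the list alone). Smooth muscle markers had 0 of 6 members higher and 0 lower (0 and 0 adjusted over the list alone) and macrophage markers 0 of 10 members higher and 0 lower (0 and 0 adjusted over the list alone). Across tissues, camera called 70 of 174 list tests in uterus, of which 16 held with an estimated correlation, and 39 of 135 in pituitary, of which 11 held. The directional fry test gave the same direction for 69 and 23 of these calls.

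Whether EE acted differently on the tissues was tested at each shared time. The tissues also differed in their control RNAs, as Dap had values on 30 pituitary and 0 uterus arrays, and handling is thus not separable from tissue. At 4 h the effect differed for 2104 of 6237 genes, more positive in uterus for 946. The uterine effect exceeded the pituitary effect by 3.34 ± 0.17 for Rasd1, 2.98 ± 0.19 for Inhbb, 2.12 ± 0.16 for Enc1 and 2.04 ± 0.15 for Tnfrsf12a, and Casp2 differed by -1.22 ± 0.09. Ribosome biogenesis genes had the more positive effect in uterus in 20 of 25 (20 adjusted over the list alone), with camera adjusted p = 5.39e-12, held at adjusted p = 0.00397 with an estimated correlation. At 8 h the effect differed for 2935 of 6124 genes, more positive in uterus for 1373, with Rasd1 at 2.48 ± 0.16, Tsr1 at 1.70 ± 0.12, the guanylate cyclase gene Gucy1a1 at -2.15 ± 0.15 and the pocket protein gene Rbl2 at -1.70 ± 0.12. Transfer RNA synthetases did so at 8 h in 15 of 16 (15 adjusted over the list alone), with camera adjusted p = 1.02e-07, held at adjusted p = 0.0123 with an estimated correlation. Estrogen-responsive uterine genes did so in 6 of 8 (6 adjusted over the list alone), with camera adjusted p = 7.63e-05, held at adjusted p = 0.0123 with an estimated correlation.

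From 24 h on the tissues still differed, for 2534 of 6323 genes at 24 h, 2276 of 6264 at 48 h and 2318 of 6006 at 72 h. Cholesterol synthesis genes had the more positive effect in uterus in 11 of 12 (11 adjusted over the list alone) at 24 h, with camera adjusted p = 2.73e-10, held at adjusted p = 0.0186 with an estimated correlation. Glycolysis genes did so in 8 of 12 (9 adjusted over the list alone) at 48 h, with camera adjusted p = 6.26e-08, held at adjusted p = 0.0115 with an estimated correlation. Mitosis genes did so in 13 of 13 (13 adjusted over the list alone) at 48 h, with camera adjusted p = 9.89e-12, lost at adjusted p = 0.0838 with an estimated correlation. Macrophage markers did so in 9 of 10 (9 adjusted over the list alone) at 72 h, with camera adjusted p = 2.28e-09, held at adjusted p = 0.0309 with an estimated correlation. Single genes were Spon1 at 24 h (1.92 ± 0.17) and Cpxm1 at 72 h (-3.15 ± 0.24).

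Controls were compared across times to show what changed without EE. In uterus 2271 of 6974 genes differed between control times. The clock gene Nr1d1 had mean log2 levels of 7.20 at 8 h and 6.10 at 24 h (adjusted p = 4.02e-14), and Mki67 of 7.59 at 8 h and 5.86 at 72 h (adjusted p = 5.88e-11). Replication genes differed in 20 of 20 (20 adjusted over the list alone), mitosis genes in 15 of 15 (15 adjusted over the list alone) and extracellular matrix genes in 25 of 37 (27 adjusted over the list alone). In pituitary 107 of 6591 genes differed between control times. Dbp, a clock output gene, had mean log2 levels of 7.99 at 8 h and 7.02 at 24 h (adjusted p = 2.85e-07). Immediate-early genes differed in 8 of 16 (10 adjusted over the list alone) and clock genes in 5 of 11 (7 adjusted over the list alone). The pituitary count was 36 with only control groups in the fit, 330 with array weights, 64 without control array 16 of 4 h, 60 without control array 66 of 48 h, 24 without control array 73 of 72 h and 35 without control array 76 of 72 h.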

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

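The tests of scaling, RNA quality, keratin and immediate-early genes, and both kinds of sample splits, were chosen after the results concerned were seen.

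From 4 h on, most genes tested in uterus passed, and array scaling or RNA quality might account for such breadth. The lowest count at 4 to 72 h, as a percentage of the reported one, was 94.03 over median centring and quantile normalization. With the Actb 3'-to-5' difference as a covariate it was 91.16. Both argue against these explanations as the whole cause. An effect of EE on the tissue, which the design names, stays open as a hypothesis.

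Keratin genes among the largest uterine rises spread widely between arrays, and arrays may hold different shares of stratified epithelium. Krt5 and Krt15 were blank on 4 control arrays. Over the 66 others the residuals of Krt6c, Krt10, Krt13, Krt14 and Sprr1a varied with those of Krt5 and Krt15 (r = 0.766, permutation p = 1e-05, the smallest it can give, 1.5e-05 adjusted over 3 relations). With blanks as 0 on all 70 arrays r was 0.8397. The residuals of Dsp, Perp, Lgals7 and Aqp3 did so as well (r = 0.873, rho = 0.885, both permutation p = 1e-05, r = 0.860 without the 2 farthest). For Krt8, Krt18 and Krt19, keratins of simple epithelium, r was 0.316 and rho 0.279 (permutation p = 0.02 and 0.05, r = 0.245 without the 2 farthest). A larger share on EE arrays as the source was tested with Krt5 and Krt15 as a covariate. With their blanks as 0 or without the 4 arrays, 15 of 15 rises at 24 to 72 h passed. The covariate changed by 1.843, -0.015, 0.317 and 2.235 at 24, 28, 48 and 72 h. It could remove little at 48 h, and at 28 h save for Krt13 and Krt14 (blank on EE arrays low in Krt5). Krt6c at 24 h went from 4.23 to 3.20 and 3.26. EE may alter Krt5 (1.86 at 72 h, adjusted p = 0.0309), so an EE effect in such cells stays a hypothesis.

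Immediate-early genes were lower with EE in pituitary at 72 h, which might rest on high controls, on low EE arrays or on a single array. Over all 18 measured members the 72 h controls averaged 0.4436 log2 above the other controls (exact permutation p = 0.0132, 3 against 12 arrays), and the 72 h EE arrays 0.0144 below the other EE arrays (exact permutation p = 0.767). This is consistent with high controls. The difference at 72 h was -0.462, and without any 1 array it stayed at or below -0.4016, which argues against a single array as the whole cause. An effect of EE on genes raised at 72 h stays open.

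Splits of the samples into groups of the same sizes tested whether chance gives as many genes. In uterus, 1 of 100 splits, the real one, gave as many at each time, which argues against chance. The real counts and the highest others were 461 and 337 at 2 h, 4034 and 2491 at 4 h, 4469 and 3006 at 8 h, 4191 and 2715 at 24 h, 4396 and 2910 at 28 h, 4018 and 2646 at 48 h, and 4106 and 2848 at 72 h. In pituitary the 10 splits are too few for a share under 0.05. There the real counts and the highest others were 102 and 13 at 4 h, 236 and 240 at 8 h (2 splits as large), 6 and 5 at 24 h, 22 and 0 at 48 h, and 178 and 0 at 72 h. The 0 are limma counts, and 632 and 916 genes had an unadjusted p under 0.05 in the real comparisons. At 8 h the split with 240 genes set control arrays 26 and 28 and EE array 33 against the rest.

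Counts of differing effects follow, each beside splits of treatment labels within times and tissues. The EE effect differed between times for 5210 genes in uterus (1 of 100 splits as large, highest other 1895) and 70 in pituitary (1 of 100, highest other 65). It differed between tissues for 2104 genes at 4 h (3 of 100, highest other 2581), 2935 at 8 h (1 of 100, highest other 1691), 2534 at 24 h (3 of 100, highest other 2615), 2276 at 48 h (3 of 100, highest other 2449) and 2318 at 72 h (1 of 100, highest other 1476). Between 28 and 4 h 2428 genes differed (4 of 100, highest other 3311). Between 28 and 24 h 568 genes differed (20 of 100, highest other 4379). A split that keeps EE apart at a single time or tissue measures the EE effect there. These splits thus cannot tell whether effects differ, nor exclude chance. Control times differed for 2271 genes in uterus (1 of 100, highest other 83) and 107 in pituitary (1 of 100, highest other 33).

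With time or tissue labels exchanged within treatment, only the real split of 100 was as large for each of these 9 differences. This argues against chance. The highest other counts were 10 for uterine times, 2 for pituitary times, 76 for 28 against 24 h and 799 for 28 against 4 h. For tissues they were 1343 at 4 h, 1259 at 8 h, 1502 at 24 h, 1541 at 48 h and 1461 at 72 h. Tissues differ in spread, so exchanging them is not exact. Levels were first moved to a common mean, which shifted 4 real counts by 1 gene, to 567, 2936, 2533 and 2319.

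Single uterus arrays stood apart from their group in 10 of 172 tests (a group and measure each), against 8.6 by chance (about 1 in 20), and groups of 3 were not tested. In Actb 3'-to-5' difference this was EE array 19 of 4 h (0.139), in Gapdh EE array 72 of 48 h (0.237). In residual spread it was control array 28 of 8 h (0.105), control array 50 of 28 h (0.150) and EE array 84 of 72 h (0.152). In intensity it was Pgr in EE array 82 of 72 h (229), C3 in EE array 71 of 48 h (1490) and EE array 84 of 72 h (4870), Igf1 in control array 50 of 28 h (453) and Mki67 in EE array 45 of 24 h (302). Probe sets with no gene or several genes stood outside the comparisons, and 339 of 1474 were higher with EE in uterus at 8 h and 240 of 1398 at 72 h.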

How the results depend on the processing

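Blanks counted as 0, genes with a value on every array compared, leaving out the arrays of widest residuals, the covariates and the permutation of numbers are tests chosen only after the data were seen, and the others were planned. Under these settings no count for uterus at 4 to 72 h, for differences in uterus or between tissues, or for uterine control times moved by over 1.5 times. Those counts at 4 to 72 h lay between 3471 and 5848. No named gene turned its direction. Of 871 values of named genes, 53 lost their call with only the compared groups in the fit, 25 with floored values, 24 with quantile normalization and 33 without the arrays of widest residuals. Of 309 list tests, 82 lost their call with an estimated correlation. Values near background limit what low genes can show.

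With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, the counts were 263 in uterus at 2 h, 26, 9 and 2 in pituitary at 4, 8 and 24 h, and 36 for pituitary control times. With limma array weights they were 194, 13, 184 and 336 in pituitary at 4, 24, 48 and 72 h, 210 for pituitary times and 330 for pituitary control times, and the cause was not tested. With floored values pituitary at 24 h had 0 genes in limma, against 389 with an unadjusted p under 0.05 before flooring, and the cause was not tested. With blanks counted as 0 pituitary at 48 h had 40, and the cause was not tested. Without the arrays of widest residuals pituitary had 8 genes at 8 h, where fewer arrays were left and the lone EE array was assumed to vary like other groups, and 37 at 48 h, for which the cause was not tested. With the Actb covariate pituitary at 8 h had 512, and the cause was not tested.

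Leaving out 1 array at a time gave 307 to 535 genes in uterus at 2 h (lowest without EE array 12). In pituitary it gave 54 to 104 at 4 h, 58 to 533 at 8 h, 0 to 5 at 24 h, 9 to 20 at 48 h and 87 to 121 at 72 h. For pituitary times it gave 40 to 116, and for pituitary control times 24 to 101. The lowest were without control array 16, EE array 34, EE array 43, control array 64, EE array 81, control array 16 and control array 73, and the 533 and 116 were without EE array 33 of 8 h. Fewer arrays leave less to test with, and no other cause was tested.

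With the title number as a replicate block across tissues, 2158 genes differed between tissues at 4 h, 2974 at 8 h, 2579 at 24 h, 2315 at 48 h and 2355 at 72 h, and no call moved by over 1.5 times. Of 27 pairs of arrays with a shared number, 7 had a correlation of deviations over 0.1 (median 0.0583, range -0.0708 to 0.153), and 13 correlated best with their own number, against 5.4 by chance (permutation p = 0.0016). This hints that numbers mark animals, which the labels do not state, and the numbers were not used as pairs.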

Other observations

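Of the tests here, that of EE given again was chosen only after the result was seen. Secretory granule genes were lower at 28 h, when 0 of 6 rose and 6 fell (0 and 6 adjusted over the list alone), with Pam, an enzyme of peptide amidation, at -1.70 ± 0.09 (camera adjusted p = 0.00392, lost at adjusted p = 0.0574 with an estimated correlation). Complement genes went both ways at 72 h, when 6 of 11 rose and 3 fell (6 and 3 adjusted over the list alone), with Cd55, which restrains complement, at 2.38 ± 0.21. The Wnt target Axin2 rose at 2 h (1.05 ± 0.11) and fell at 48 h (-1.13 ± 0.11). Genes with values on every array of a group and on none of the other were, in uterus, 58 with EE and 30 with control at 4 h and 35 and 146 at 8 h, against up to 4 and 3 in other splits. In uterus at 2 h they were 13 and 0, against up to 15 in other splits. In pituitary such genes numbered 27 at 4 h, 56 at 8 h, 27 at 24 h, 37 at 48 h and 49 at 72 h, against up to 45, 36, 27, 33 and 27 in the 9 other splits.

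In the controls Dbp, a clock output gene, was highest at 8 h in uterus (log2 7.67) and in pituitary (7.99), and Bmal1 was lowest at 8 h (5.97 and 6.20). The largest rise among probe sets with no gene or several genes was by 3.21 in uterus at 72 h.

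A hypothesis concerns early uterine rises that were seen again at 28 h. The prediction for the controls was written before their values were seen. If EE was given again shortly before 28 h, genes with a 4 h effect would change alike from 24 to 28 h. Spearman's rho across 6704 genes, which are not independent replicates, was 0.5923, and 129 of 132 genes at least 2-fold higher at 4 h had a positive difference (92 passed), as 68 of 68 lower genes had a negative one (42 passed). This restates the rises that prompted it, so it does not support repeated dosing, which the labels do not give and which stays open. Time of day in the controls was tested by the median control change of those higher genes from 24 to 28 h, which was -0.03553 (quartiles -0.122 and 0.0485) and argues against it. A time of day at which EE acts more strongly may also account for it and stays open.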
